A study of Mus musculus with 2 samples.

How the data were processed

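Total RNA from LMO2 siRNA and control siRNA G1E-ER-GATA-1 cells was hybridised to 2 two-colour Agilent mouse arrays with the control arm in Cy5 and the LMO2 siRNA arm in Cy3, per the labels. Spots were quantified with Agilent Feature Extraction 9.1.3.1 with local background, per the file headers. The deposited scanner files give each spot's brightness as intensity on a linear scale, as mean signal, local background and processed signal in each channel. The processed signals were background-subtracted, corrected for position and dye-normalized by the scanner software, per the file headers, which also give a multiplicative ratio for position in each channel and a p-value for each spot's log ratio. The deposited log10 ratios are red over green, and the series' own table held those log10 values for all 45018 spots of each array within 0.005 log10 units, with a median of 0 on each array, so its scale and direction are known. The genome build behind the array design is not given in the sources used here. Both arrays sit on the same slide, so slide and scan could not be tested as batches.

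Background was corrected from mean signals and local background with normexp (offset 50) in limma 3.58.1 (R 4.3.3). Each array was normalized by loess with control spots at weight 0, and ratios were turned to LMO2 siRNA over control. Control spots (1639) were then left out. The remaining 43379 spots form 41174 distinct probes, 245 of them printed in 10 spots, which were averaged. Spots with outlier flags were kept, and leaving them out was an alternative. Of the probes, 24844 were named by RefSeq accession through a gene table of assembly GRCm38.p6, used for names only, 9636 kept the array file's symbol and 6694 have no symbol. A probe was used where at least 1 channel was well above background on both arrays, which 24735 probes met, and a gene is its brightest such probe. Of 14314 genes, 5191 had further probes, and for 2538 genes the probes differed in sign.

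Each gene's mean log2 ratio was tested against 0 with lmFit and eBayes (1 residual and 28 prior degrees of freedom), with Benjamini-Hochberg adjustment over genes at 0.05. With 1 comparison of 2 arrays, no outlier test, split of samples or comparison between groups applies. On simulated values for 14314 genes of this comparison, 100% of 100 genes changed 1.5-fold and 100% of 100 genes changed 2-fold were recovered with 16 false calls. Variances were drawn from the model's own fitted prior and genes were independent, so this recovery checks the code and not the accuracy of calls in the data. Drift shared by both arrays and dye effects were not simulated. Probes printed in 10 spots differed between the arrays with an SD of 0.13, against 0.02 from spot noise, a gap that technical repeats can also show. The arrays were counted as 2 replicates because the labels number them so.

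A probe saturated in both channels on both arrays is given no fold, nor is one saturated in the control channel.

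The 26 gene lists, the tests and the alternatives were fixed before the data were examined. Lists were tested with camera at its preset correlation, with Benjamini-Hochberg adjustment over lists of 3 or more measured members, and set against 10000 random lists drawn from 20 brightness classes. The preset correlation takes members of a list as nearly independent, and the random lists draw unrelated genes. For genes regulated together both can therefore overstate the evidence, and neither shows how a list repeats between cultures. Camera with an estimated correlation and fry were alternatives. Both rest on 1 residual degree of freedom here, so a list that failed in them is little evidence either way. The named genes are Lmo2, every measured member of the LMO2 complex list, the 10 largest increases and 10 largest decreases with adjusted p under 0.05, 1 sign on both arrays and a symbol that is not a clone, predicted-gene or accession name, and up to 4 members with the largest absolute log2 ratio from every other list. Other genes named in the text were chosen after their values were seen. Alternatives covered background correction, normexp offset (10), normalization, filters, saturated and outlier-flagged spots, probe summaries, variance priors, a separate-channel fit, the series' own table, a 1.5-fold threshold and each array alone. The position correction divides background-corrected signals by the scanner's position ratio before loess. It was added after seeing the data, as were list tests without saturated probes and the rule that combines the tests with, and without, position correction and with processed signals.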

Results

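The series compared G1E-ER-GATA-1 cells that had received siRNA against Lmo2 with the same cells that had received control siRNA. These mouse erythroid cells lack GATA-1 and carry a GATA-1 fusion that estradiol switches on, and both arms were kept in estradiol for 24 h after transfection. Lmo2 encodes a bridging protein of the transcription factor complex that GATA-1 joins in erythroid cells, and the comparison asks which transcripts differ when Lmo2 is lowered during estradiol-induced maturation. RNA of both arms was hybridised together on 2 two-colour Agilent arrays, each with 43379 spots for genes or transcripts. The LMO2 siRNA arm was labelled with Cy3 and the control arm with Cy5 on both arrays, so a dye effect cannot be separated from the siRNA effect. Between 55.8% and 68.2% of spots were well above background per channel. The labels number the arrays as replicates without saying that they came from separate cultures, so p-values reflect only these samples, whose spread may be technical. With 28 prior against 1 residual degree of freedom, a gene's limma p-value rests mostly on variance pooled over genes. It therefore does not show how well that gene's ratio repeats between the arrays. Every ratio below is LMO2 siRNA over control siRNA, as mean log2 ratio ± SD over both arrays (n = 2), and the number of arrays limits its precision.

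Lmo2 itself fell by 1.92 ± 0.14 on the log2 scale, a 3.77-fold lower signal with LMO2 siRNA (adjusted p = 3.6e-21, limma). The log2 ratio was -1.82 on replicate 1 and -2.02 on replicate 2. Its probe read 1254 and 1138 intensity units in the LMO2 siRNA channel against 8336 and 8571 in the control channel, with neither channel saturated. The targeted gene therefore ran in the direction the labels give on both arrays.

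Gsn, which encodes the actin-severing protein gelsolin, had the largest rise and was 6.38-fold higher (log2 ratio 2.67 ± 0.16, adjusted p = 4.0e-24). Fcgr3, an Fc receptor for immunoglobulin G, was 4.64-fold higher (2.21 ± 0.04), and Pirb, an inhibitory receptor of myeloid and B cells, was 3.96-fold higher (1.98 ± 0.08). Vim, which encodes the intermediate filament vimentin, rose by 1.88 ± 0.10, and Lgals3, the lectin galectin-3, by 1.90 ± 0.17. The scaffold gene Ahnak (1.99 ± 0.08), the unconventional myosin gene Myo1g (1.96 ± 0.05) and the adaptor gene Dok2 (1.98 ± 0.11) rose by similar amounts. Pdxk, which encodes pyridoxal kinase, rose by 2.02 ± 0.04, and Hey1, a transcriptional repressor downstream of Notch, by 1.87 ± 0.01.

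After Lmo2, the riboflavin transporter gene Slc52a3 had the largest fall seen on both arrays (-1.53 ± 0.03, 2.88-fold lower, adjusted p = 2.4e-19). Pfkfb4, which encodes an enzyme that sets fructose 2,6-bisphosphate, fell by 1.26 ± 0.07, and Erfe, the erythroid hormone erythroferrone that lowers hepcidin, fell by 1.12 ± 0.03. Uba3, a subunit of the NEDD8-activating enzyme, fell by 1.07 ± 0.08, Fgl1 by 1.07 ± 0.09, Dcaf12l2 by 1.07 ± 0.10 and Mcemp1 by 1.05 ± 0.13. Dpf2 also ranked among the 10 largest decreases, but it rested on 1 array, with -0.22 on replicate 1 and -2.60 on replicate 2. Its limma adjusted p was still 5.5e-06.

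**Figure D1:**
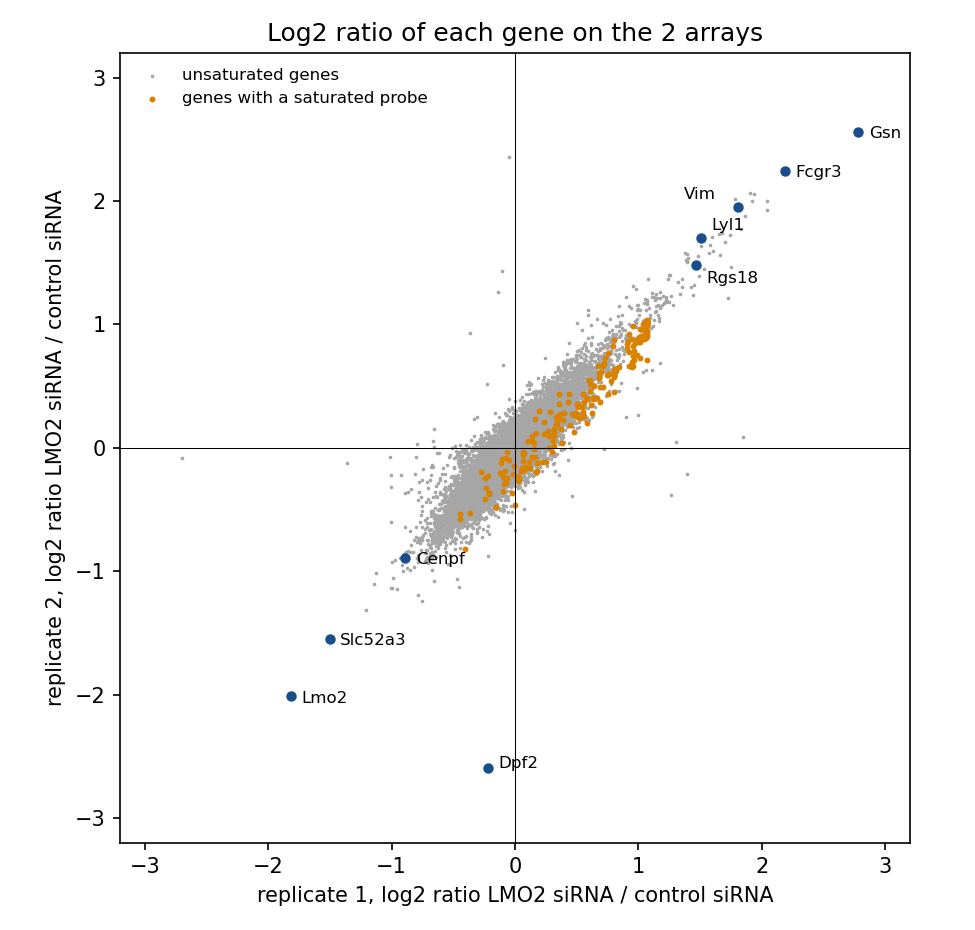
Log2 ratio of LMO2 siRNA over control siRNA for each of the 14314 measured genes, replicate 1 on the x axis and replicate 2 on the y axis, with genes that have a saturated probe in orange and 9 named genes in blue. Gsn reads 2.78 and 2.56, Lmo2 -1.82 and -2.02, and Dpf2 lies off the diagonal.

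Across 14314 measured genes, limma called 3509 higher and 3923 lower at an adjusted p of 0.05. That is 51.9% of them, so calls of some members do not by themselves set a gene list apart. The log2 ratios of the arrays correlated at r = 0.90 across genes, which are not independent replicates, 0.87 with position correction and 0.74 in processed signals. The dye orientation and a drift described below are shared by both arrays and can add to r. Most of the called differences were small, with a median log2 ratio of 0.29 among genes called higher and -0.28 among genes called lower. There were 146 genes 2-fold or more higher on both arrays, 55 of them with a saturated probe, and 6 genes 2-fold or more lower on both arrays, but with median centring in place of loess these counts were 18 and 618. The log2 ratio also drifted with a spot's row on the array by about the size of the typical call, and the scanner's own factor for position removed most of that drift. With that factor applied, 2895 genes were called higher and 2582 lower. With the scanner's processed signals, 972 were called higher and 485 lower. That test had only 2.2 prior degrees of freedom, so a gene that misses its threshold is weak evidence of no change. "Rose" and "fell" are used below for unsaturated genes called in the same direction with all 3 sets of values, a rule set after seeing the data, which 771 higher and 363 lower genes met. The size of a change depended on the processing: in processed signals the log2 ratio was larger by over 1.5 times for 450 of these 1134 genes, 366 of them among the 567 dimmer ones, and smaller by over 1.5 times for 26, 25 of them among the 567 brighter ones. With position correction it was larger by that factor for 118 and smaller for 79. Median centring put the median of all genes at -0.40 and turned the sign of 25 of 133 named genes, among them Gata2, Plek, Birc3, Stat2, Gabarap, Pkm and Eno1. "Called" refers to the limma test without position correction.

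**Figure D2:**
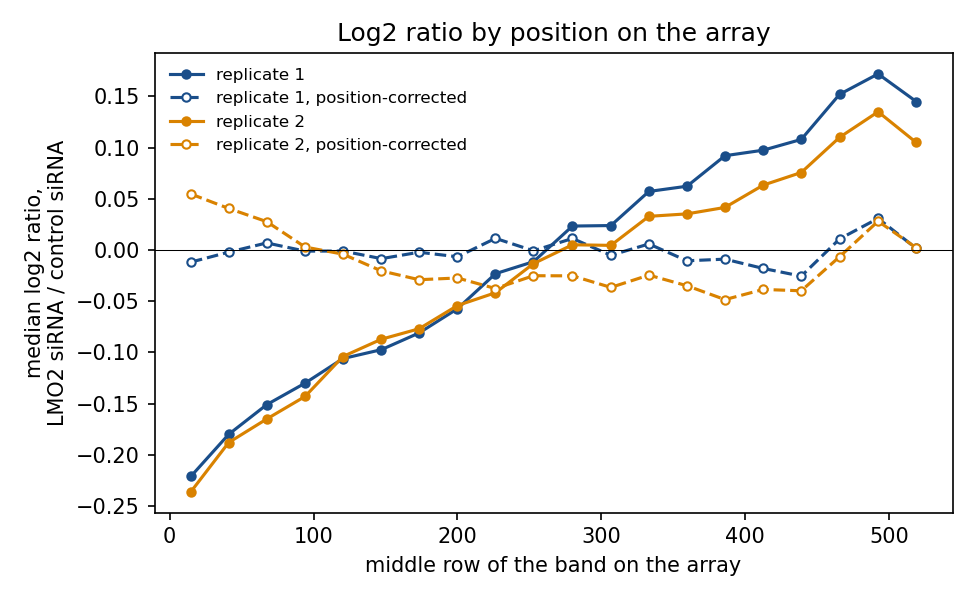
Median log2 ratio of LMO2 siRNA over control siRNA in 20 bands of rows on each array, with the middle row of the band on the x axis, replicate 1 in blue and replicate 2 in orange, filled points without and open points with position correction. Uncorrected medians run from -0.22 to 0.17 on replicate 1 and from -0.24 to 0.14 on replicate 2.

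Members of the LMO2 complex list moved in both directions. Lyl1, a basic helix-loop-helix factor related to Tal1, rose 3.04-fold (1.60 ± 0.14, adjusted p = 2.3e-19). Lmo4 (0.74 ± 0.08), Cbfb (0.62 ± 0.03) and Gata2 (0.43 ± 0.06) also rose, while Ssbp2, which encodes a protein that stabilises LDB1, fell by 0.75 ± 0.0033. Gfi1b, a repressor that acts with GATA-1, was called lower at -0.83 ± 0.06, and read -0.43 with position correction and -0.41 in processed signals, where its adjusted p was 0.051. Tcf12 was called lower at -0.59 ± 0.06, although another of its 3 probes read 0.31. Tal1 (0.38), Ldb1 (-0.44), Gata1 (-0.24), Cbfa2t3 (-0.17) and Runx1 (-0.14) were called without meeting the rule for all 3 sets of values, and another probe of Cbfa2t3 read 0.00043. Tcf3 (0.07), Ssbp3 (0.01), Ssbp4 (0.03), Ldb2 (-0.07) and Lmo1 (0.12) did not pass. Probes differed in sign for Tcf3 and Ssbp3, whose other probe read -0.31 and -0.29. Lmo1 was not well above background in the control channel. Zfpm1, which encodes the GATA-1 partner FOG-1, was saturated in the control channel on both arrays, so its fold is not given. In all, 6 of 19 members were called higher, 8 lower with Lmo2 included and 5 neither, and the list as a whole did not stand apart (camera adjusted p = 0.98).

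Progenitor genes that GATA-1 is known to repress were higher with LMO2 siRNA. Of 20 measured members, 12 were called higher, 4 lower and 4 neither, and 9 rose by the stricter rule. Besides Vim and Lyl1, these were Rgs18, a regulator of G-protein signalling (1.48 ± 0.01), the adhesion receptor gene Cd44 (1.02 ± 0.04), Myb (0.81 ± 0.10), Meis1 (0.78 ± 0.07), the stem cell factor receptor gene Kit (0.69 ± 0.01), Gata2 and Spi1. A dimmer probe of Cd44 read -0.03. Bmi1 (-0.33), Etv6 (-0.24), Flt3 (-0.15) and Runx1 (-0.14) were called lower. The list median of 0.32 lay above all 10000 random lists of matched brightness, and camera called the list (adjusted p = 1.4e-04). Both take genes as the units, with members nearly independent, so neither shows how the difference repeats between cultures. With an estimated correlation camera's adjusted p was 0.90. That test rests on 1 residual degree of freedom, and 0 of the 26 lists reached an unadjusted p under 0.05 in it, so it cannot decide. The fry test, which sets a list against no change and not against other genes, gave an adjusted p of 0.10. It too rests on 1 residual degree of freedom, and no list had a lower adjusted p in it. With median centring the list median was -0.14, against -0.40 for all genes.

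Genes of DNA replication and mitosis were lower. Of 31 measured proliferation genes, 25 were called lower, 2 higher and 4 neither, with a list median of -0.40 (camera adjusted p = 4.2e-09). This p-value likewise takes members as nearly independent. With an estimated correlation, where camera called no list at all, the adjusted p was 0.90. In fry, against no change and also on 1 residual degree of freedom, the adjusted p was 0.17. With median centring the list median was -1.09, against -0.40 for all genes. By the stricter rule 7 fell and none rose. They were the kinetochore gene Cenpf (-0.89 ± 0.0037), the mitotic kinase gene Plk1 (-0.70 ± 0.06), the replication helicase genes Mcm5 (-0.64 ± 0.0036) and Mcm4 (-0.60 ± 0.03), Cdc20 (-0.53 ± 0.03), Ccnb2 (-0.44 ± 0.08) and Ccne1 (-0.32 ± 0.11). With position correction Cenpf read -0.59, Plk1 -0.44 and Ccne1 -0.56. Ccna2 (-0.71) and Bub1b (-0.70) were called lower and missed the threshold in processed signals, with adjusted p of 0.053 and 0.050. Mcm6 (0.18) and Rrm2 (0.23) were called higher but read -0.04 and -0.01 with position correction.

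**Figure D3:**
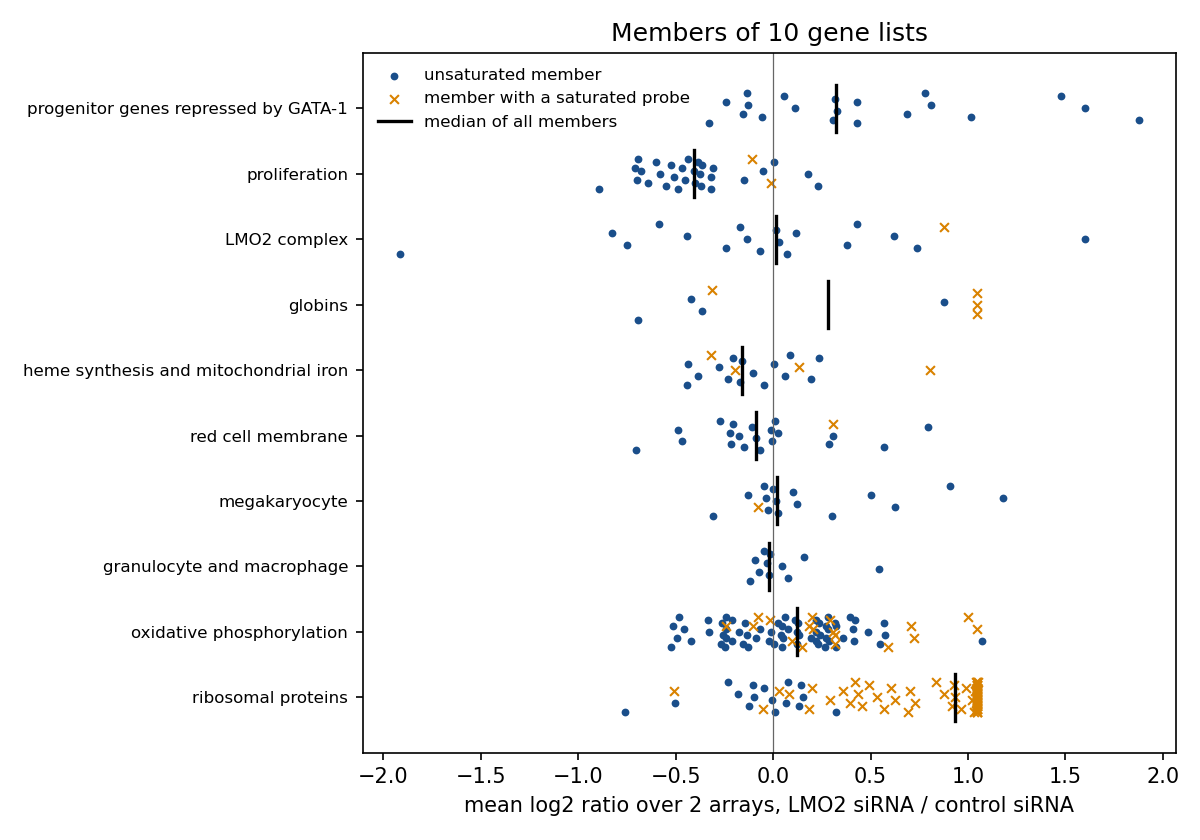
Mean log2 ratio over 2 arrays, LMO2 siRNA over control siRNA, of each measured member of 10 gene lists, with unsaturated members as blue dots, members with a saturated probe as orange crosses and the median of all members as a black bar. The progenitor list has a median of 0.32 and the proliferation list of -0.40, and ribosomal protein genes pile up at 1.05 where both channels are saturated.

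Of 81 measured ribosomal protein genes 64 were called higher (list median 0.93, camera adjusted p = 6.0e-27, and 0.90 with an estimated correlation), but 65 of the 81 had a saturated probe. The 35 members saturated in both channels on both arrays, Rps14, Rplp2 and Rps20 among them, all read between 1.04 and 1.05, and no fold is given for them. The 16 unsaturated members had a median of -0.03 (camera adjusted p = 0.76), with 3 called higher and 4 lower. Oxidative phosphorylation genes were called as a list (39 of 83 higher, 22 lower, median 0.12, adjusted p = 0.044, and 0.90 with an estimated correlation). Without saturated probes anywhere on the array the adjusted p was 0.35, but the list was called higher when position correction was added (adjusted p = 0.031, and 0.93 with an estimated correlation) and in processed signals (adjusted p = 0.0053, and 0.94 with an estimated correlation). With median centring it was called lower (adjusted p = 0.0018, and 0.83 with an estimated correlation). Cox7a1, a cytochrome c oxidase subunit, rose by 1.07 ± 0.12, while Cox6a1, Atp5b and Atp5a1 had saturated probes. Cholesterol synthesis genes were called lower (13 of 23 lower, 2 higher, median -0.17, adjusted p = 0.044, and 0.90 with an estimated correlation), and without saturated probes anywhere on the array the adjusted p was 0.078. None of the 23 members was saturated, so the list median stayed at -0.17 there. It was -0.08 with position correction besides and -0.08 in processed signals. Cyp51 (-0.70 ± 0.04) and Mvk (-0.66 ± 0.07), which encode enzymes of the pathway, fell, although a dimmer probe of Mvk read 0.01. Fdps (-0.56) and Acat2 (-0.46) were called lower without meeting the stricter rule.

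Erythroid gene groups were mixed. Among globins, the adult genes Hbb-bt, Hba-a1 and Hba-a2 were saturated in both channels, so no fold is given, and near-identical copies may share signal. The embryonic globin gene Hbb-bh1 rose by 0.88 ± 0.04, whereas 3 other unsaturated globin genes fell. With saturated members counted, 4 of 8 measured members were called higher, 4 lower and 0 neither (camera adjusted p = 0.45). The saturated genes Hbb-bt, Hba-a1 and Hba-a2 are among those called higher. Without saturated probes 4 members remained, with a median of -0.39 (camera adjusted p = 0.40). It was -0.33 with position correction and -0.55 in processed signals (camera adjusted p = 0.27 for each). In heme synthesis and mitochondrial iron, 10 of 19 genes were called lower, 3 higher and 6 neither (median -0.16, adjusted p = 0.45), with Slc25a38 (-0.44), Isca1 (-0.44) and Uros (-0.39) called lower and Glrx5 saturated in the control channel. With position correction and without saturated probes the list was called lower (median -0.18, adjusted p = 0.031, and 0.93 with an estimated correlation). No member met the stricter rule. Red cell membrane genes gave 9 lower, 5 higher and 7 neither of 21 (median -0.09, adjusted p = 0.67). Icam4 rose by 0.79 ± 0.07, Xk was called higher at 0.57, and Spnb1 (-0.70) and Slc4a1 (-0.49) were called lower. Iron uptake and storage genes gave 5 higher, 4 lower and 6 neither of 15 (adjusted p = 0.67), with Fth1 and Ftl1 saturated, Pcbp1 at 0.49 and Aco1 at -0.48. Erythroid transcription factors and EPO signalling gave 7 higher, 12 lower and 6 neither of 25 (adjusted p = 0.72), with rises of Socs1 (0.64 ± 0.19) and Sox6 (0.63 ± 0.03).

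Markers of other cell types were called in part, but in none of these lists was the share called above the 51.9% of all measured genes. In the megakaryocyte list 5 of 16 genes were called higher, 1 lower and 10 neither (adjusted p = 0.13), with rises of the platelet glycoprotein genes Gp1ba (1.18 ± 0.05) and Gp5 (0.62 ± 0.01), and of Rab27b (0.91 ± 0.01) and Plek (0.50 ± 0.09). With position correction and without saturated probes the megakaryocyte list was called higher (median 0.18, adjusted p = 0.036, and 0.93 with an estimated correlation). Among mast cell and basophil genes 6 of 15 were called higher, 1 lower and 8 neither (adjusted p = 0.22). Hdc, which makes histamine, rose by 1.22 ± 0.08 and Cpa3 by 0.37 ± 0.13, while Mitf was called at 0.38 and Srgn at -0.33. Granulocyte and macrophage genes gave 2 higher, 0 lower and 9 neither of 11 (adjusted p = 0.81), with Cd68 at 0.55 ± 0.05, Ltf at 0.16 ± 0.02, Csf1r at -0.12 and Itgam at -0.09. Lymphocyte genes gave 0 higher, 2 lower and 7 neither of 9 (adjusted p = 0.63), where Cd3e read -0.34, Dntt -0.23 and Cd79a -0.06. In limma endothelial genes gave 0 calls among 7, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.98), with Nos3 at 0.13, Esam at -0.10, Sox17 at -0.07 and Flt1 at 0.05. Pluripotent stem cell genes gave 2 higher, 1 lower and 6 neither of 9 (adjusted p = 0.87), with Dppa5a at 0.38, Tcl1 at -0.19, Klf2 at 0.16 and Dppa4 at -0.06.

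Among p53 targets 8 of 20 were called lower, 3 higher and 9 neither (adjusted p = 0.20), and Gdf15 (-0.74 ± 0.08), Eda2r (-0.73 ± 0.02) and Trp53inp1 (-0.71 ± 0.03) fell. In glycolysis and hypoxia 8 of 23 were called higher, 6 lower and 9 neither (adjusted p = 0.72). The glucose transporter gene Slc2a1 fell by 0.90 ± 0.02, Pkm rose by 0.63 ± 0.03 and Eno1 by 0.58 ± 0.08, and Aldoa was saturated in the control channel. Interferon response genes gave 6 higher, 1 lower and 11 neither of 18 (adjusted p = 0.45), with rises of Irf1 (0.48 ± 0.07) and Stat2 (0.39 ± 0.02). Cell cycle exit genes gave 5 higher, 6 lower and 6 neither of 17 (adjusted p = 0.74), with Trib3 at -0.61, Rbl1 at -0.56 and Cdkn1b at -0.56, where another Cdkn1b probe read 0.32. Apoptosis genes gave 7 higher, 6 lower and 8 neither of 21 (adjusted p = 0.87), with a rise of Birc3 (0.55 ± 0.01). ATF4 and unfolded protein response genes gave 8 higher, 6 lower and 10 neither of 24 (adjusted p = 0.67), with Slc7a5 at 0.56. Autophagy and mitochondrial clearance genes gave 7 higher, 9 lower and 9 neither of 25 (adjusted p = 0.87), with a rise of Gabarap (0.63 ± 0.03) and Bnip3 at -0.58. Histones gave 6 higher, 1 lower and 4 neither of 11 (adjusted p = 0.077), with rises of Hist1h4i (0.64 ± 0.20) and Hist2h2bb (0.57 ± 0.03). Reference genes gave 6 higher, 3 lower and 6 neither of 15 (adjusted p = 0.063), with a rise of Ywhaz (1.22 ± 0.02). Eef1a1 and Rplp0 were saturated in both channels. Histones and reference genes were called higher in processed signals (adjusted p = 0.017 for each, and 0.79 with an estimated correlation), but not without saturated probes (adjusted p = 0.12 and 0.13).

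Among the genes above said to have risen or fallen, several differed by over 1.5 times in size under other processing. With position correction Erfe read -0.74, Lmo4 0.49, Cyp51 -0.47, Mvk -0.40, Gabarap 0.42, Eda2r -0.47 and Socs1 1.02. In processed signals Gata2 read 0.66, Rgs18 2.48, Spi1 1.01, Cpa3 1.25, Gp5 1.31, Sox6 1.21, Cd68 0.93, Ltf 0.69, Irf1 1.16 and Hist2h2bb 1.12. A dimmer probe of the same gene read a smaller change for several, among them Pdxk (0.63), Ahnak (0.53), Slc52a3 (-0.97) and Ssbp2 (-0.34). Further such genes were Lmo4 (0.19), Cbfb (0.09), Sox6 (0.15) and Cenpf (-0.19). For others a dimmer probe read a larger change, among them Pirb (2.67), Plek (0.79) and Ltf (0.29).

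Adjusted over the list alone, the counts were as above for 19 of the 26 lists. The exceptions were progenitor genes (12 higher, 5 lower), p53 targets (4 higher, 8 lower), autophagy (8 higher, 9 lower), cholesterol synthesis (2 higher, 14 lower), ribosomal proteins (65 higher, 5 lower), oxidative phosphorylation (42 higher, 23 lower) and reference genes (7 higher, 3 lower). The median, mean and camera direction differed in sign for the LMO2 complex, cell cycle exit, granulocyte and macrophage, and endothelial lists, none of which was called.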

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

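All tests weighed here were chosen after the result they bear on had been seen.

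Added E1A control transcripts, which belong to no gene comparison, read a median of 1280 intensity units in Cy3 and 185 in Cy5, against 41.4 and 47.8 at negative control probes, and all 10 E1A probes were brighter in Cy3. Among 2986 measured probes with no gene symbol, which the gene comparison leaves out, 10 were 2-fold or more higher and 1 was 2-fold or more lower on both arrays.

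The first pattern is a drift of log2 ratios along the rows of both arrays, from a median of -0.22 to 0.17 on replicate 1 and -0.24 to 0.14 on replicate 2 over 20 bands of rows. Deviations of repeated spots from their probe's own mean correlated at 0.886 between the arrays over 1440 spots. Such spots read the same transcript, so the value argues against target abundance and goes with position on the array. With position correction the correlation was 0.33 and the bands spanned -0.03 to 0.03 and -0.05 to 0.05. No biological explanation of the remaining drift was tested.

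The second pattern is the higher reading of ribosomal protein genes. Unsaturated members had a median of -0.0271, and the upper end of its 95% interval, 0.0755, argues against a general rise on these arrays of ribosomal protein transcripts with an unsaturated brightest probe. The interval comes from resampling the 16 genes and holds no spread between arrays or cultures. For 91 genes that have both kinds of probe, the median was 0.58 through the saturated probe and -0.0516 through an unsaturated one, and for the 27 ribosomal protein genes among them 1.05 and -0.09, which is consistent with saturation as a source of the reading. For 38 ribosomal protein genes no unsaturated probe passed the filter, so a true change in those genes cannot be told apart from saturation.

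The third pattern is that progenitor genes were higher and proliferation genes lower. Their medians with position correction and without saturated probes, 0.291 and -0.396 (camera adjusted p = 3.5e-05 and 1.3e-10, and 0.93 for each with an estimated correlation), argue against position on the array as the whole cause. Dye bias, gene-specific or through probe base composition, cannot be told apart from an effect of the siRNA, since the arrays hold only 1 dye orientation and a fit on base composition, which left medians of 0.321 and -0.414, took only 0.425% of the variance, too little for a test. Granulocytes or macrophages in the LMO2 siRNA cells cannot be told apart from the siRNA effect. Their 9 listed genes well above background in both channels had a median of -0.0146 (95% interval from resampling the genes, -0.09 to 0.16). In processed signals that interval, -0.27 to 0.69, held the progenitor median of 0.30. Abundant transcripts of such cells were near background in Cy3 (S100a8 3.63 and Lyz2 13.3 intensity units above it) and in Cy5 (6.81 and 28.2), but the level that a given share of such cells would bring is not known.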

How the results depend on the processing

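Alternatives with position correction, and list tests without saturated probes, were chosen after seeing the data, and the rest were planned. Lmo2 stayed lower and past the threshold in all 17 alternatives with a test, from -2.57 to -1.90 (adjusted p 1.7e-135 to 0.026), and read -2.02 and -1.82 with either replicate alone. No paired analysis was possible because the series has 1 group, and both arms already share each array. With 1 array left no test can be made, so the counts of called genes have no value without a replicate. Signal over background limits dim genes: with both channels required well above background 13124 genes were tested.

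Counts of genes higher with LMO2 siRNA and genes lower with LMO2 siRNA moved from 3509 and 3923 to 972 and 485 with processed signals, 898 and 426 with the series' own table, 425 and 9239 with median centring, and 544 and 256 at 1.5-fold or more. Each probe by itself gave 5338 and 6028 probes, because more items were tested. With position correction 2582 were lower. The 1.5-fold threshold only adds a size cut to the same test. Prior degrees of freedom were 28 in the main setting, 2.2 with processed signals and 2.14 with the series' table, so the latter 2 tests pooled less variance over genes. Of the genes called in the main setting, 0 turned their call in either. Whether the weaker pooling accounts for the fewer calls was not tested, nor were the causes in the remaining settings. The share of higher calls was 47.2%, against 66.7% with processed signals, 67.8% with the series' table and 4.4% with median centring, which put the median of all genes at -0.40. Of genes called higher, 2274 kept their call with position correction and 2 turned, and of those called lower 1936 kept it and 37 turned.

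Counts of genes 2-fold or more higher on both arrays moved from 146 to 225 with processed signals and with the series' table, 18 with median centring, 91 without saturated probes, 97 with the mean over probes, and 79 with position correction and no saturated probes. The number of genes 2-fold or more lower on both arrays moved from 6 to 41 with processed signals and the series' table, 618 with median centring, 12 for single probes and 3 with position correction, with or without saturated probes. On a single array the lower count was 12 to 16. Of 133 named genes, 72 were called with processed signals and 70 with the series' own table. The cause was not tested.

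The number of gene lists called went from 5 to 0 with an estimated correlation in camera (0 at an unadjusted p under 0.05), 0 with fry, which sets each list against no change (8 at an unadjusted p under 0.05), 6 with processed signals, 7 with no filter on dim probes, 14 with median centring, 3 with the mean over probes and with ranks, 2 without saturated probes, and 3 in processed signals without them. Camera with an estimated correlation and fry rest on 1 residual degree of freedom here, so their 0 calls say little about any list. With an estimated correlation the adjusted p was 0.901 for ribosomal proteins, proliferation, progenitor genes repressed by GATA-1, cholesterol synthesis and oxidative phosphorylation. In fry these were 0.102, 0.172, 0.102, 0.259 and 0.201. Cholesterol synthesis also lost its call in processed signals (0.137, and 0.164 without saturated probes), with the mean over probes (0.0756), with ranks (0.0542), without saturated probes (0.0785) and with position correction besides (0.0763). Oxidative phosphorylation lost it with the mean over probes (0.0556), with ranks (0.0579) and without saturated probes (0.349), and turned lower with median centring (0.00183). Ribosomal proteins turned lower and uncalled without saturated probes (0.758), with position correction besides (0.21) and in processed signals without them (0.522). With median centring 9 further lists were called: higher than other genes for mast cell and basophil (0.0011), granulocyte and macrophage (0.021), megakaryocyte (0.025) and endothelial genes (0.025), and lower for heme synthesis and mitochondrial iron (0.00052), p53 targets (0.0034), red cell membrane (0.011), cell cycle exit (0.014) and erythroid transcription factors and EPO signalling (0.014), each 0.83 with an estimated correlation. With no filter on dim probes histones and reference genes were called higher (0.037 each, and 0.84 with an estimated correlation). The cause was not tested beyond saturation.

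Median centring turned the sign of Tal1 (-0.36), Tcf3 (-0.60), Gata2 (-0.20), Ssbp3 (-0.74), Ssbp4 (-0.57), Glrx5 (-0.015), Pcbp1 (-0.32), Xk (-0.00075), Mitf (-0.20), Plek (-0.19), Klf2 (-0.62), Cdkn2d (-0.39), Birc3 (-0.011), Stat2 (-0.14), Slc7a5 (-0.12), Dnajb9 (-0.20), Hspa5 (-0.39), Gabarap (-0.070), Sqstm1 (-0.42), Pkm (-0.0034), Eno1 (-0.037), Hist2h2ac (-0.16), H2afv (-0.42), Atp5a1 (-0.095) and Actb (-0.14), against the shifted median of -0.40. Of these genes, Glrx5, Hist2h2ac, H2afv and Atp5a1 were saturated in the control channel on both arrays. Their values only describe how the reading moved with the processing and are not folds. Without saturated probes Rps20 read -0.12 and Rplp0 -0.20 through other probes, and with position correction besides Rps20 read -0.0056, Atp5b -0.081 and Rplp0 -0.15. Bcl2l1 read 0.010 as a mean over probes and Ssbp3 -0.20 with position correction, with or without saturated probes.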

Other observations

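The galectin and cytochrome c oxidase symbol families were higher with LMO2 siRNA in a screen made after seeing the data. Families of 8 or more unsaturated genes that share a symbol root were tested with camera on position-corrected values, and 6 of 191 passed Benjamini-Hochberg adjustment, of which 2 also passed without position correction. With position correction, 6 of 8 galectin genes (Lgals) passed the limma threshold as higher and 0 as lower (median 0.36, camera adjusted p = 0.0038, and 0.98 with an estimated correlation). Lgals3 read 1.90 (2.28 with position correction), Lgals1 1.71, Lgals9 1.20 and Lgals8 0.54. With median centring the Lgals median was 0.22, against -0.40 for all genes. With position correction, 10 of 18 genes with the root Cox passed the limma threshold as higher and 0 as lower (median 0.21, camera adjusted p = 0.029, and 0.98 with an estimated correlation). Their median was -0.37 with median centring, and 10 of the 18 also belong to the gene lists already described. The families Olfr, Rbm, Cep and Mcm were called lower with position correction (adjusted p of 0.013, 0.016, 0.029 and 0.050, and 0.98 for each with an estimated correlation), with medians of -0.07, -0.15, -0.13 and -0.27. Without it their medians were -0.05, -0.22, -0.21 and -0.28 and they were not called (adjusted p of 0.33, 0.11, 0.11 and 0.19). With median centring their medians were -0.07, -0.83, -0.69 and -0.86, against -0.40 for all genes. The Olfr median thus lay above that of all genes there, so its direction depended on the normalization.

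A hypothesis made after seeing the data is that the cells may have responded less to GATA-1, which would lower erythroid genes. It was first tested on 3 erythroid lists picked after their values were seen and then, since that choice favours the hypothesis, on all 5. Without saturated probes, the 5 lists joined had a median of -0.128 with position correction (camera p = 0.021), -0.09 without it (p = 0.074) and -0.12 in processed signals (p = 0.14), and p was 0.23 to 0.52 with an estimated correlation. The 3 lists joined had a median of -0.17 with position correction (p = 7.7e-04), -0.15 without it (p = 0.055) and -0.17 in processed signals (p = 0.015), and p was 0.27 to 0.42 with an estimated correlation. The test on all 5 lists passed in only 1 of these 3 sets of values, so the hypothesis stays open. The values with an estimated correlation rest on 1 residual degree of freedom and cannot decide it.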
